A study of Rattus norvegicus with 6 samples.

How the data were processed

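The data were single-colour microarrays of total RNA from renal cortex, 1 array for each of 6 rats, and groups were taken from the sample titles: 3 control and 3 o-anisidine hydrochloride animals, which the series design describes as biological replicates. Per the labels' protocols, the RNA was amplified and labelled with Cy3, the dose was 700 mg/kg/day for 4 weeks, and controls received water. The route of dosing is not given in the sources used here.

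The deposited scanner files hold, per the file headers, spot intensity values from Agilent Feature Extraction 10.7.1.1, and the submitters' processing notes name Agilent Feature Extraction 10.7. The processed intensity used here is, per the file headers, the signal of each spot after that software's background subtraction and detrending, with no scaling between arrays. The median signal and median local background intensity are the uncorrected pixel values, per the file headers. The other deposited columns used were flags, per the file headers, that mark spots well above background, saturated spots and outlier spots. The array's design was annotated on the rn4 assembly, per the file headers.

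The series also has a table of values by the authors, which holds an intensity scaled between arrays. Its scaling was not given in the sources used here and was found by comparison: each column equals the processed signal of 1 scanner file divided by that array's 75th percentile, on a linear scale with no centring of genes, and the column medians lie between 0.104 and 0.108. Each column matched the scanner file of another replicate of the same group (r = 1.00 across probes, against 0.991 to 0.993 for its own), in the same rotation in both groups. Columns 1, 2 and 3 of the controls matched control 3, control 1 and control 2, and those of o-anisidine matched o-anisidine 3, o-anisidine 1 and o-anisidine 2. Membership of the groups is unaffected. Replicate numbers below follow the scanner files, and which of the numberings is right stays unknown.

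Each array held 62976 spots, and control spots were left out, leaving 61657 probes. Values were log2 of the processed signal minus the array's 75th percentile over these probes. Probes with an outlier flag on any array (16), a step the written plan did not list, and probes not well above background on all 3 arrays of at least 1 group were left out, which kept 42036. The files carried no gene symbol, so each probe's accession was matched without version to the RefSeq gene table of the GRCr8 assembly: 27460 probes matched 15284 symbols, and 34197 kept the array's own identifier. The plan had named the array's gene name column, which these files lack. That table was used for names only, and no coordinates are given because its assembly differs from that of the array. A gene was represented by its kept probe with the highest mean, giving 31087 genes, 12015 of them with a symbol.

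Groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided, no covariates) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The moderated test had 4 residual and 2.11 prior degrees of freedom. Gene lists of 5 or more measured members were tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. The 33 lists named 771 genes, of which 706 were on the array (16 entries through a synonym) and 666 were tested. They covered cell types a cortex sample could hold, foreign compound handling, DNA damage, cell division, injury, immunity, metabolism and stress, and the results of each are given in the text. A gene not well above background on every array of a group is given as a bound, the mean log2 of the brighter group against the mean over the dim arrays of the higher of the array's lowest signal that was well above background and the probe's own.

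The genes named in the text were chosen by a rule: among genes with a symbol past the threshold whose groups did not overlap, the 12 largest rises and 12 largest falls, which took all 9, and in each list the 2 largest rises and falls past the threshold or, where none passed, the member with the smallest p, which for the cholesterol synthesis list is not reported here. Other members are given as examples and were chosen after their values were seen, as were the genes named only in the closing section. The lists, the rule, the tests and most alternatives were fixed before the data were examined.

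The statistics were tested on simulated data for the comparison of o-anisidine with control over 31087 genes, in 5 runs. Of changes of log2 1, 2 and 4, 66.3%, 87.8% and 99.1% were recovered, with 60 false calls in all. Each run held far more changed genes than the 11 higher and 8 lower genes called in the real data, which loosens the adjusted threshold. These shares may therefore overstate recovery in the real comparison. A list with every member shifted by log2 1 was called in 5 of 5 runs and an unshifted list in 0, both at an unadjusted p under 0.05. Lists with smaller shifts were not simulated. Noise was drawn independently for each gene, and the lists were random genes. The runs therefore do not show how often a list of correlated genes is called falsely.

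The alternatives were other background corrections, normalizations, filters, ways to combine probes and variance models, the authors' table, slide as a fixed or random block, the slide with both groups alone, the replicate number as a block, each array left out in turn, other thresholds and other tests of lists. The planned normexp correction was written for a mean signal column that these files lack and was not run. Normexp with an offset of 50 on the median signals took its place and was chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.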

Results

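The series measured gene expression in the renal cortex of male Sprague-Dawley rats, bought at 5 weeks of age, that received water (control) or o-anisidine hydrochloride at 700 mg/kg/day for 4 weeks. o-Anisidine is an aromatic amine. The design question was which transcripts of the renal cortex differed between 3 control and 3 treated animals, each measured on 1 single-colour (Cy3) Agilent array. Between 41670 and 43630 of 61657 probes were well above background on each array, no spot was saturated, and the 75th percentile of the processed signal lay between 923 and 1031. After scaling, arrays of the control group correlated at 0.993 to 0.994 across 31087 genes, arrays of the o-anisidine group at 0.992 to 0.993, and arrays of different groups at 0.990 to 0.992. The first principal component held 33.5% of the variance and had all 3 control arrays on one side and all 3 treated arrays on the other. The number of arrays, 3 per group, limits the precision of every value below.

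After 4 weeks of o-anisidine the renal cortex carried RNA of Cyp1a1, a monooxygenase induced through the aryl hydrocarbon receptor, that was not well above background on any control array. Genes of red blood cells and their precursors rose with it: Rhd and Kel, which encode blood group proteins, Ahsp, which encodes a chaperone of alpha globin, and Hemgn, a nuclear protein of erythroid cells. Alox15, an arachidonate lipoxygenase, and Cd52, a surface glycoprotein of leukocytes, also rose. Cryga and Crygd, which encode gamma crystallins of the eye lens, fell. Cyp1a1 had a mean log2 signal relative to the 75th percentile of -8.20 ± 0.05 (SD, n = 3) in controls and -1.58 ± 0.04 (n = 3) after o-anisidine, which makes it at least 23.8-fold higher (limma with Benjamini-Hochberg adjustment, adjusted p = 1.69e-06). For this bound the signal of each control array was replaced by the lowest signal that was well above background there. The adjusted p was computed without that replacement.

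Alox15 rose 8.76-fold, a log2 change of 3.13 (SE 0.25, adjusted p = 0.038), from -2.67 ± 0.24 to 0.46 ± 0.47 (SD, n = 3 each). Rhd rose by a log2 change of 2.61 (SE 0.12, adjusted p = 0.00477), Kel by 2.17 (SE 0.08, adjusted p = 0.0020) and Hemgn by 1.97 (SE 0.12, adjusted p = 0.0101). Ahsp rose by 2.34 (SE 0.21, adjusted p = 0.0419) and Cd52 by 2.12 (SE 0.17, adjusted p = 0.038). Second kept probes of Ahsp and Hemgn gave log2 changes of 2.49 (SE 0.24) and 2.47 (SE 0.19). Cryga fell by 4.11 on the log2 scale (SE 0.22, adjusted p = 0.00598), from 3.96 ± 0.39 in controls to -0.15 ± 0.21 (SD, n = 3 each). Crygd fell by 4.05 (SE 0.20, adjusted p = 0.00558) on its brighter probe, while its other kept probe had a log2 change of -0.04 (SE 0.16). In the plot of the named genes per array, every treated value lies on the same side of all 3 control values, as the rule that chose these genes required.

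**Figure D1:**
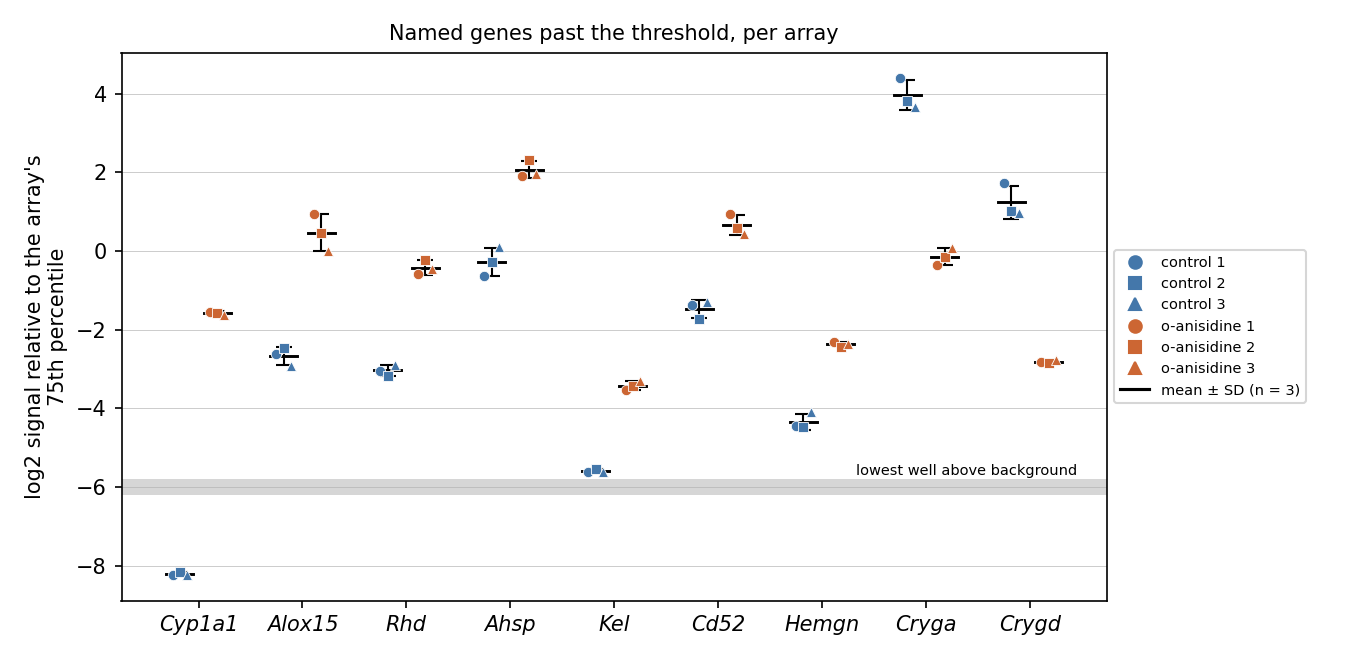
Log2 signal relative to the array's 75th percentile (vertical axis) of the 9 named genes past the threshold; each point is 1 array, blue for control and orange for o-anisidine, and bars give the mean ± SD (n = 3). The grey band spans the lowest signals that were well above background on the 6 arrays; Cyp1a1 lies under it on all 3 control arrays and at a mean of -1.58 on the treated arrays.

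In all, 11 genes were higher and 8 lower after o-anisidine among 31087 tested (limma, Benjamini-Hochberg, two-sided). Each had a fitted difference of at least 2-fold, but for genes not well above background in 1 group that difference rests on signal near background, and the bounds of 2 of the lower genes are under 2-fold. Of these, 7 higher and 2 lower genes carried a symbol in the GRCr8 table. Among array identifiers that this table did not match, XM_001069014 rose by a log2 change of 2.13 (SE 0.16, adjusted p = 0.0294). TC609231 was at least 3.15-fold higher, being not well above background in controls. NM_001108718 fell by 2.06 on the log2 scale (SE 0.07, adjusted p = 0.0011), and TC592348 was at least 19.1-fold lower, being not well above background after treatment. At an unadjusted p under 0.05 there were 1977 higher and 1598 lower genes. The 2 groups did not overlap for 18.4% of genes, against 10% that chance gives for 3 arrays against 3. That 10% takes no account of the probe filter, which used the groups, or of the slides, which were not even over the groups.

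The slide entered neither group evenly, since all controls and o-anisidine 3 shared 1 slide and o-anisidine 1 and 2 were on the other. With slide as a fixed block 2 genes were higher and 1 lower, and on the slide that held both groups 1 was higher and 1 lower. The within-slide log2 changes of the 9 named genes, which the block gives too, were 6.58 for Cyp1a1, 2.66 for Alox15, 2.58 for Rhd, 2.24 for Ahsp, 2.28 for Kel, 1.90 for Cd52, 1.98 for Hemgn, -3.90 for Cryga and -4.01 for Crygd. The fitted values of Cyp1a1 in this paragraph, and their adjusted p, rest on control signals that were not well above background. Only Cyp1a1 and Kel kept an adjusted p under the threshold with the block (3.31e-04 and 0.0446), and only Cyp1a1 within the slide (0.00972). Without control 1, 2 or 3 the counts were 3, 4 and 4 higher and 4, 4 and 3 lower, and without o-anisidine 1, 2 or 3 they were 8, 16 and 2 higher and 4, 5 and 1 lower. Of the 8 and 16 higher genes, 3 and 4 were among the original 11. Background correction by normexp gave 67 higher and 17 lower genes, with a log2 change of 2.49 for Cyp1a1, 0.98 for Kel and 1.30 for Hemgn, and a variance model with trend and robust estimation gave 91 and 29. With no filter on dim probes Alox15, Ahsp and Cd52 lost the call (0.0999, 0.107 and 0.0999), and with the mean of all kept probes Crygd had a log2 change of -2.04.

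Genes of cell division formed the list with the largest median log2 change. All 24 measured genes of the mitosis list were higher after o-anisidine on each treated array than on every control array, with a median log2 change of 1.28, or 2.43-fold. The list rose against all other genes (limma's camera with a preset correlation, Benjamini-Hochberg over 33 lists, adjusted p = 1.07e-27). That call was lost at an adjusted p = 0.317 with an estimated correlation, the highest of 20 alternatives, of which the lowest was 5.84e-37. No member passed the threshold over all genes, and all 24 passed when adjusted over the list alone. Racgap1, a regulator of cytokinesis, had the smallest p of the list, with a log2 change of 0.90 (SE 0.10, adjusted p = 0.0891). Kif20a, a kinesin of late mitosis, had 1.86 (SE 0.24, adjusted p = 0.0993) and Cdk1, the kinase that drives entry into mitosis, 1.51 (SE 0.22, adjusted p = 0.108). The median shift of the list from the control mean was 1.42, 0.86 and 1.53 on o-anisidine 1, 2 and 3, the last of these being the value within the control slide, and between -0.22 and 0.15 on the controls.

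The red blood cell list rose with a median log2 change of 1.19 over 11 members (1.09 with Rhag, which was not well above background in controls, at its bound; camera adjusted p = 1.50e-11). The call was lost at an adjusted p = 0.154 with an estimated correlation, the highest of 20 alternatives, the lowest being 6.00e-14. Ahsp alone passed over all genes, and 9 members rose when adjusted over the list alone. The globin gene Hbb-b1 had a log2 change of 1.30 (SE 0.19, adjusted p = 0.108), Hba-a1 had 0.90 (SE 0.14, adjusted p = 0.112), and Alas2, the erythroid enzyme that starts haem synthesis, had 2.13 (SE 0.28, adjusted p = 0.0993). Median shifts of this list were 1.30, 1.24 and 1.01 on o-anisidine 1, 2 and 3. The mitosis list rose in the same comparison of groups, which by itself shows no link between the lists. Its shift was highest on o-anisidine 3 (1.53), where that of the red blood cell list was lowest. The haem and iron handling list, which holds enzymes and transporters found in many tissues, was not called (median 0.10, adjusted p = 0.232). In it, Alad, the second enzyme of haem synthesis, had the smallest p (log2 change -0.36, SE 0.07, adjusted p = 0.148).

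DNA replication genes rose much less than mitosis genes, with a median log2 change of 0.14 over 28 members, 25 of them above 0 (camera adjusted p = 2.50e-04). With an estimated correlation the adjusted p = 0.478, the highest of 20 alternatives, and the lowest was 4.47e-07, without control 1, where the median was 0.25. Cdc6, which loads the replicative helicase, was the only member higher when adjusted over the list alone (log2 change 0.83, SE 0.09, adjusted p over all genes 0.0888). Genes regulated by p53 rose by a median of 0.12 over 24 members (adjusted p = 0.0477), with none past the threshold over all genes or adjusted over the list alone. That call was lost at an adjusted p = 0.317 with an estimated correlation, the highest of 20 alternatives, the lowest with camera being 0.0238, while fry, which tests a list against no change, gave 0.0043. It was also lost with slide as a block (median 0.07, adjusted p = 0.0778), within the control slide (0.0580), with the replicate number as a block (0.0608), with no filter on dim probes (0.295), with all 6 arrays well above background (0.0554) and without control 2, control 3, o-anisidine 1 or o-anisidine 3 (0.137, 0.0636, 0.0537 and 0.142). Gadd45a, a growth arrest gene, had the smallest p (0.29, SE 0.10, adjusted p = 0.361), and Cdkn1a had a log2 change of 0.16 (SE 0.15, adjusted p = 0.722). The DNA repair list was not called (median 0.05, adjusted p = 0.232), and Ung, a uracil glycosylase, had a log2 change of -0.36 (SE 0.10, adjusted p = 0.301).

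Among genes of foreign compound handling, the aryl hydrocarbon receptor list rose with a median log2 change of 0.48 over 5 measured members, unchanged with Cyp1a1 at its bound (camera adjusted p = 0.0029, computed with its fitted log2 change of 6.63). Its median shift was 0.36, 0.03 and 0.54 on o-anisidine 1, 2 and 3, the value of o-anisidine 2 lying within the range of the controls, -0.01 to 0.09. The call was lost at an adjusted p = 0.226 with an estimated correlation, the highest of 19 alternatives, the lowest with camera being 0.00129, while fry, which tests a list against no change, gave 1.13e-06. The call was lost too with no filter on dim probes (median 0.22, adjusted p = 0.0762). Cyp1a1 was the only member past the threshold over all genes, and the mean log2 change of the list, 1.44 with its fitted value, lay well above the median. Whether the list would be called without Cyp1a1 was not tested. Adjusted over the list alone, 2 members were higher and 1 lower. Ugt1a6, a glucuronosyltransferase, had a log2 change of 0.48 (SE 0.09, adjusted p over all genes 0.149), and Ahrr, the repressor of the receptor, had -0.90 (SE 0.29, adjusted p = 0.357). Glutathione transferases rose by a median of 0.31 over 19 genes, 17 of them above 0 (adjusted p = 1.94e-06), with 0 past the threshold over all genes and 4 adjusted over the list alone. For them the adjusted p = 0.375 with an estimated correlation, the highest of 20 alternatives, and the lowest was 1.35e-08. Gstp1 had a log2 change of 0.78 (SE 0.12, adjusted p = 0.115) and Gstm1 of 2.79 (SE 0.72, adjusted p = 0.266).

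NRF2 targets, the genes of the antioxidant response, rose by a median of 0.23 over 22 members, 20 of them above 0 (adjusted p = 2.23e-05), with 0 past the threshold over all genes and 1 adjusted over the list alone. With an estimated correlation the adjusted p = 0.226, the highest of 20 alternatives, of which the lowest was 1.89e-07. The median was 0.35 within the control slide and 0.36 without control 3. Srxn1, a sulfiredoxin, had a log2 change of 1.17 (SE 0.16, adjusted p = 0.0993) and Hmox1, the inducible haem oxygenase, of 1.70 (SE 0.59, adjusted p = 0.373). The other kept probe of Srxn1 had a smaller log2 change of 0.62 (SE 0.19). Nqo1, which belongs to both the NRF2 and the aryl hydrocarbon receptor lists, had 0.94 (SE 0.39, adjusted p = 0.440), with o-anisidine 2 at -2.61 inside the range of the controls. The list of other xenobiotic oxidation and conjugation was not called (median 0.11 over 26 members, adjusted p = 0.0693), with 3 members higher when adjusted over the list alone. Its smallest p belonged to Ugt1a2 (0.55, SE 0.09, adjusted p = 0.116).

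Genes of cholesterol synthesis rose slightly and together, with a median log2 change of 0.19 over 24 members and 22 of them above 0 (camera adjusted p = 4.78e-10). The call was lost at an adjusted p = 0.154 with an estimated correlation, the highest of 20 alternatives, the lowest being 3.28e-11. None passed over all genes, and 8 were higher when adjusted over the list alone. Idi1 and Cyp51, enzymes of the pathway, had log2 changes of 0.67 and 0.64 (SE 0.12 each, adjusted p = 0.134 and 0.139). The lists of PPAR-alpha and fatty acid oxidation (median -0.07, adjusted p = 0.253), oxidative phosphorylation (0.02, adjusted p = 0.623), the circadian clock (0.08, adjusted p = 0.802) and the kidney's endocrine and hormone axes (-0.13, adjusted p = 0.232) were not called. Their members of smallest p were Pex11a (log2 change -0.44, adjusted p = 0.488), Cox5a (0.15, adjusted p = 0.499), Bhlhe40 (0.41, adjusted p = 0.357) and Esr1 (-0.71, adjusted p = 0.145).

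Kidney injury markers rose by a median log2 change of 0.35 over 22 members (camera adjusted p = 0.00129), with 18 of them above 0. The call was lost at an adjusted p = 0.593 with an estimated correlation, the highest of 20 alternatives, the lowest being 4.44e-06, and also with no filter on dim probes (0.0762). Without o-anisidine 1 the median was 0.20, with the call kept. No member passed over all genes, and adjusted over the list alone 2 were higher and 1 lower. Krt19, a keratin of simple epithelia, had a log2 change of 2.88 (SE 0.34, adjusted p = 0.0894), Clu, a secreted chaperone, had 1.31 (SE 0.26, adjusted p = 0.161), and the chemokine gene Ccl2 had -0.80 (SE 0.14, adjusted p = 0.137). Havcr1, which encodes the injury marker KIM-1, differed widely between treated animals: its log2 signal was 0.46, -4.39 and -3.02 on o-anisidine 1, 2 and 3, against -4.85, -3.61 and -5.23 on the controls (log2 change 2.25, SE 1.23, adjusted p = 0.539). Spp1, or osteopontin, was at 6.39, 3.16 and 5.16 against a control mean of 3.08 (adjusted p = 0.440), and Fgb, a fibrinogen chain, at 2.76, -0.93 and 0.19 against -1.10 (adjusted p = 0.513). The last 3 genes were singled out after their values were seen. The median shift of the list was 0.71, 0.12 and 0.26 on o-anisidine 1, 2 and 3, the value within the control slide being 0.26.

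**Figure D2:**
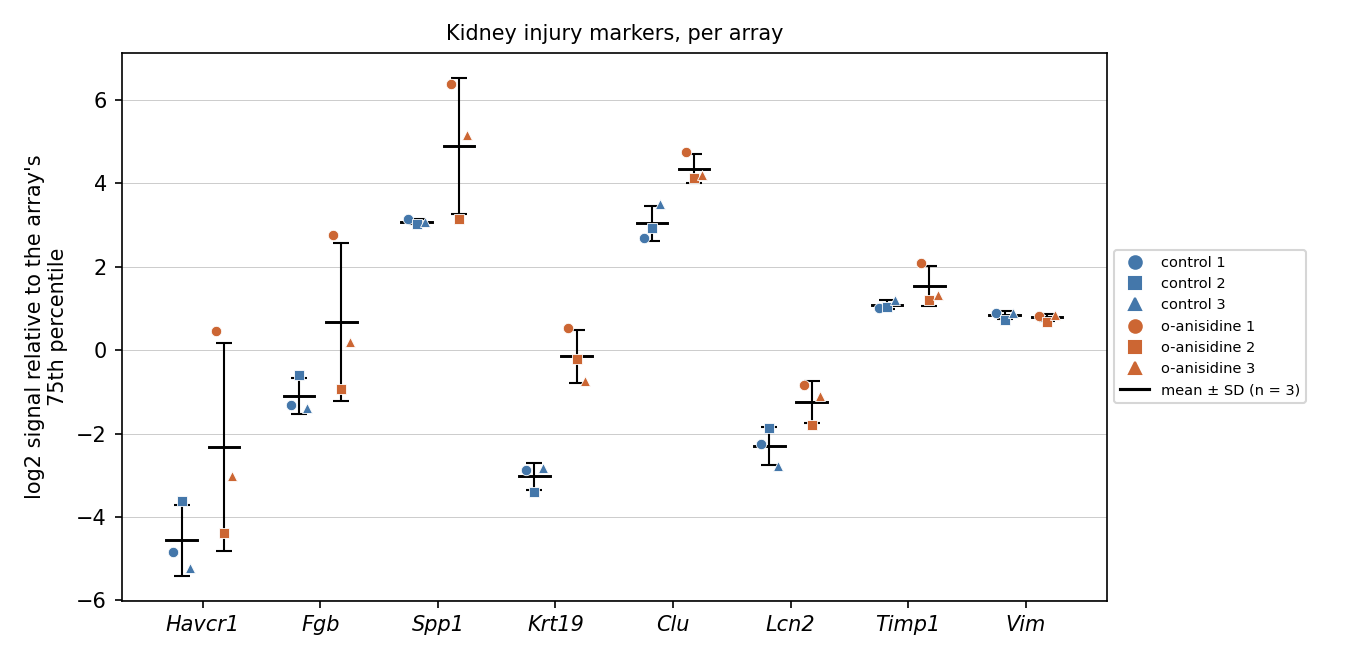
Log2 signal relative to the array's 75th percentile (vertical axis) of 8 kidney injury markers, chosen for the plot after their values were seen; each point is 1 array, blue for control and orange for o-anisidine, and bars give the mean ± SD (n = 3). Havcr1 runs from -4.39 to 0.46 among the treated arrays, while Krt19 lies above all controls on each of them.

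Markers of the nephron's cell types moved little. The collecting duct list fell, with a median log2 change of -0.13 over 18 members (camera adjusted p = 0.0136), and the call was lost at an adjusted p = 0.593 with an estimated correlation, the highest of 20 alternatives, the lowest being 5.59e-04. It was also lost with slide as a block (median -0.10, adjusted p = 0.330) and without control 2 or o-anisidine 1 (median -0.05 and -0.03, adjusted p = 0.0817 and 0.295), while without control 3 or o-anisidine 2 the median was -0.21 and -0.22. Scnn1b, a subunit of the epithelial sodium channel, was the only member lower when adjusted over the list alone, with a log2 change of -0.55 (SE 0.07, adjusted p over all genes 0.101), and Aqp2, the vasopressin-regulated water channel, had -0.58 (SE 0.22, adjusted p = 0.412). Proximal tubule transport (median 0.04 over 34 members, adjusted p = 0.259), proximal tubule metabolism (0.04 over 33, adjusted p = 0.298), thick ascending limb and distal tubule (-0.11 over 17, adjusted p = 0.0813) and podocyte (-0.11 over 17, adjusted p = 0.0516) lists were not called, though the last 2 passed the threshold under 7 and 9 of the 20 alternatives. Without control 3, o-anisidine 2 or o-anisidine 3 the ascending limb list had adjusted p of 0.00299, 0.031 and 0.0395 and the podocyte list of 0.0289, 0.0146 and 0.0446. Slc22a12, the urate transporter, had a log2 change of 0.59 (SE 0.09, adjusted p = 0.112), Hnf4a, a transcription factor of proximal tubule cells, -0.71 (SE 0.11, adjusted p = 0.115), Slc8a1 -0.57 (adjusted p = 0.152) and Plce1 -0.40 (adjusted p = 0.368). Other kept probes gave smaller falls, of -0.28 and -0.51 for Hnf4a and of -0.24, -0.41 and -0.30 for Slc8a1.

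Markers of other cells that a cortex sample could hold were mostly flat. The endothelium list had a median of 0.05 (adjusted p = 0.802), with Eng at a log2 change of -0.42 (SE 0.08, adjusted p = 0.159), and fibroblast and extracellular matrix genes had -0.08 (adjusted p = 0.253), with Ccn2 at 0.85 (SE 0.34, adjusted p = 0.432). The adipocyte list (median 0.00, adjusted p = 0.830), the adrenal cortex list (0.17 over 6 members, adjusted p = 0.346) and the urothelium and papilla list (0.08 over 7 members, adjusted p = 0.802) were not called either. Ucp1, Cyp11b2 and Upk1a had the smallest p in these, with log2 changes of -0.51, 0.35 and 0.45 (adjusted p = 0.207, 0.405 and 0.459).

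Lymphocyte genes fell, with a median log2 change of -0.34 over 18 members and 3 of them above 0 (camera adjusted p = 1.16e-04). With an estimated correlation the adjusted p = 0.453, the highest of 20 alternatives, and the lowest was 4.14e-07. With normexp the median was -0.15, and without o-anisidine 2 it was -0.21. Nkg7, a granule protein of cytotoxic cells, was the only member lower when adjusted over the list alone (log2 change -0.53, SE 0.11, adjusted p over all genes 0.161). Interferon response genes fell by a median of 0.22 over 27 members, none past the threshold over all genes or adjusted over the list alone (adjusted p = 0.00188). For that list the adjusted p = 0.593 with an estimated correlation, the highest of 20 alternatives, the lowest being 1.75e-06. Within the control slide its median was -0.04 (adjusted p = 0.330 with slide as a block), and without o-anisidine 2 it was -0.09 (adjusted p = 0.120). Usp18, a protease induced by interferon, had a log2 change of -1.25 (SE 0.28, adjusted p = 0.207). Macrophage and myeloid genes were not called (median -0.02, adjusted p = 0.708), with S100a9, a calcium-binding protein of neutrophils and monocytes, at 1.37 (SE 0.22, adjusted p = 0.115). Nor were the lists of complement (-0.11, adjusted p = 0.674), ER stress and amino acid response (-0.01, adjusted p = 0.830), heat shock (-0.05, adjusted p = 0.389) and immediate early genes (0.02, adjusted p = 0.232). Cfi, Trib3, Cryab and Ier3 had the smallest p in these lists, with log2 changes of 0.44, -0.38, 1.03 and 0.39 (adjusted p = 0.172, 0.148, 0.368 and 0.266). Within the control slide the immediate early list had a median shift of 0.40 (adjusted p = 2.33e-04 with slide as a block).

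**Figure D3:**
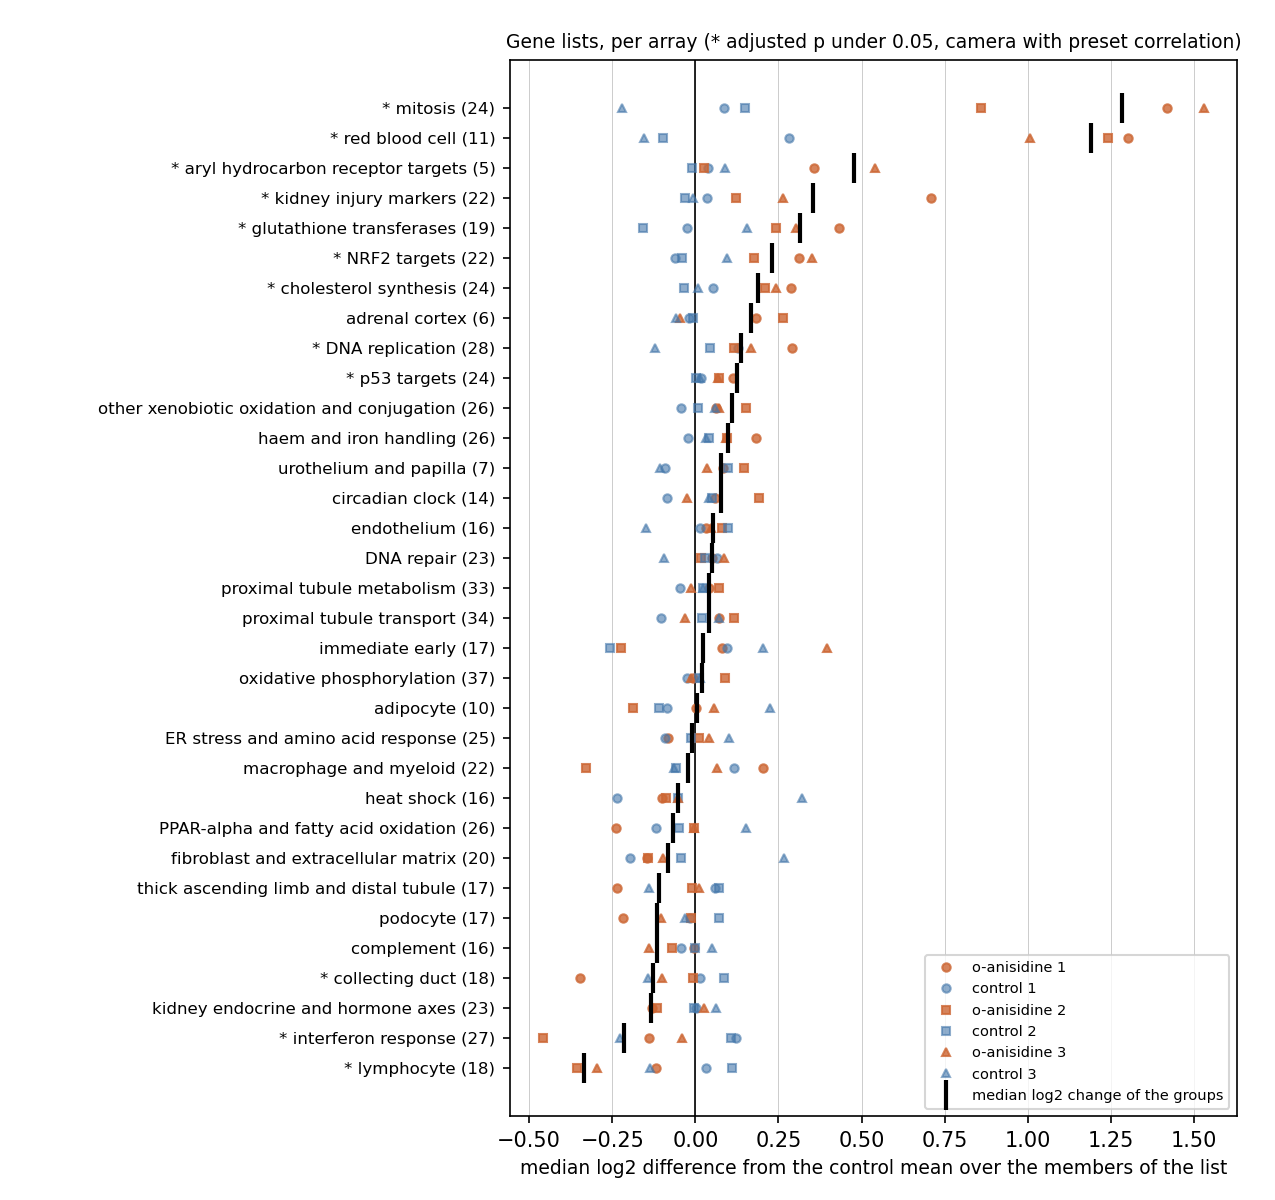
Median log2 difference from the control mean (horizontal axis) over the members of each of the 33 lists, with the number of members in brackets; orange points are the 3 treated arrays, blue points the 3 controls, and black bars the median log2 change between the groups. The mitosis and red blood cell lists have medians of 1.28 and 1.19, and lists marked with an asterisk passed the threshold with the preset correlation.

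With the preset correlation, 9 lists rose and 3 fell of the 33 tested, and with an estimated correlation 0 did. The directional test of fry called 7 lists as higher and 0 as lower, and these include other xenobiotic oxidation and conjugation (adjusted p = 0.0403), which camera did not call. The rises that fry did not call were those of glutathione transferases (adjusted p = 0.0960), DNA replication (0.246) and kidney injury markers (0.314). Within the control slide the medians of the called lists other than those named above with their slide values were 1.01 for red blood cell, 0.24 for cholesterol synthesis, 0.30 for glutathione transferases, 0.35 for NRF2 targets, 0.17 for DNA replication, 0.54 for aryl hydrocarbon receptor targets and -0.30 for lymphocyte, each still called with slide as a block. The median shift lay within the range of the controls on o-anisidine 2 for DNA replication, on o-anisidine 1 for lymphocyte, on o-anisidine 1 and 3 for interferon response and on o-anisidine 2 and 3 for collecting duct.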

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

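The normexp setting below was chosen after seeing the data, and all other settings were fixed before the data were examined. Over all alternatives run, no named gene and no called list turned its direction. Of 170 values of the 9 named genes past the threshold, 118 kept the call, and of 239 values of the 12 called lists, 203 did. For 31 other named genes, 11 of 589 values passed the threshold, and for the 21 lists not called, 33 of 420 did. The main counts were 11 genes higher, 8 lower, 9 lists higher and 3 lower. Normexp gave 67 and 17 genes and 6 lower lists, of which 11 higher and 6 lower genes were the same as in the main counts, and raised the share of higher genes from 57.9% to 79.8%. Quantile normalization gave 6 lower lists, trend and robust estimation 91 and 29 genes and 5 lower lists, and no filter on dim probes 5 higher genes and 6 lower lists. Requiring all 6 arrays well above background gave 5 lower genes, and each probe on its own 19 higher probes. Cyp1a1 and, with it, the aryl hydrocarbon receptor list have no value when all 6 arrays must be well above background. Slide as a fixed block gave 2 and 1 genes and 1 lower list, and the slide with both groups alone, where the lone treated array is assumed to vary like the controls, 1 and 1 genes and 1 lower list. An adjusted p under 0.01 left 3 and 4 genes. An estimated correlation between genes left 0 lists higher and 0 lower, and fry 0 lower. The blocked and left-out fits have fewer arrays or residual degrees of freedom by construction, and beyond this the cause was not tested.

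Leaving out each array in turn gave 2 to 16 higher genes, 1 to 5 lower genes, 8 to 11 higher lists and 2 to 6 lower lists. Between 2 and 4 of the 11 higher genes and 1 and 4 of the 8 lower genes were still called. Alox15, Ahsp and Cd52 lost the call without each array, at adjusted p of 0.0539 to 0.147, 0.0624 to 0.174 and 0.0601 to 0.129. Without o-anisidine 3, Rhd, Hemgn, Cryga and Crygd lost it too (0.0539, 0.0561, 0.0539 and 0.0539), and Hemgn also without control 1, control 2 or o-anisidine 1 (0.0755, 0.0731 and 0.0605). Of the lists not called, podocyte passed the threshold under 9 of the 20 alternatives, ascending limb under 7, other xenobiotic under 6, endocrine and immediate early under 3 each, and fatty acid oxidation under 2. Besides the first 2, those past it without 1 array were fatty acid oxidation, fibroblast and heat shock without control 1 (0.0331, 0.020 and 0.0238), other xenobiotic without control 3 or o-anisidine 1 (0.046 and 0.0226), macrophage and immediate early without o-anisidine 2 (0.0129 and 0.00183), and endocrine without o-anisidine 3 (0.0343).

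With the replicate number as a block 1 gene was higher and 0 lower (Cyp1a1, adjusted p = 0.00212), and 8 lists were higher and 3 lower. The numbers do not pair the animals: deviations from the group means of arrays with the same number correlated at 0.02, 0.08 and 0.01. At an unadjusted p under 0.05 the unblocked comparison had 1598 lower genes.

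The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 11 higher and 8 lower genes against at most 1 in either direction in any other split, and 1 of the 10 gave as many of each. For lists the real split gave 9 higher and 3 lower against up to 11 in 1 direction elsewhere, with 3 and 9 of the 10 splits giving as many. The absolute median of the mitosis list was 1.28 against at most 0.81 in the other splits, and that of the red blood cell list 1.19 against at most 0.66, but camera called these lists in 5 and 3 of the other splits too. It called the other lists of the 12 in 3 or 4 of them, except p53 targets (0) and the aryl hydrocarbon receptor list, which was too small there to test. For 4 called lists another split gave a larger absolute median: NRF2 targets (0.23 against 0.28), DNA replication (0.14 against 0.16), interferon response (0.22 against 0.27) and collecting duct (0.13 against 0.26). Probes close to background limit the folds of dim genes, which are given as bounds.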

Other observations

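The genes in the first paragraph, and the tests of explanations below, were chosen after their values were seen, except that slide as a block was a setting fixed beforehand. A further 22 genes with a symbol were higher and 6 lower at an adjusted p between 0.05 and 0.10 (limma, Benjamini-Hochberg). The groups of 3 arrays did not overlap for any of them, which follows largely from this selection on p. Fkbp5, a co-chaperone that glucocorticoids induce, had a log2 change of 1.69 (SE 0.16, adjusted p = 0.0617). Slc38a3, a glutamine transporter, had 1.76 (SE 0.20, adjusted p = 0.0888), Slc39a4, a zinc importer, 0.93 (SE 0.10, adjusted p = 0.0888), and Rgcc, a regulator of the cell cycle, 0.75 (SE 0.09, adjusted p = 0.0888). Pbk and Pttg1, 2 further genes of dividing cells, had 1.72 and 1.54 (SE 0.20 and 0.19, adjusted p = 0.0892 and 0.0993). The largest value on the lower side was that of Mapk10, a stress kinase not well above background on any treated array, at least 2.82-fold lower (adjusted p = 0.0536). The chemokine gene Cxcl1 had -0.92 (SE 0.12, adjusted p = 0.0993) and Il21r, a cytokine receptor, -0.64 (SE 0.08, adjusted p = 0.0922).

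The mitosis genes rose on treated arrays of both slides. On o-anisidine 3, the 1 treated array on the controls' slide, the values argue against slide or scan day as the whole cause. With slide as a block the median of the list was 1.53, higher than the 1.28 without it. On that slide all 24 members lay above every control array, and the median shift of the controls was at most 0.15. The call was kept with the block, where some other lists lost theirs. That is given no weight here, because how often camera calls a list of correlated genes falsely was not measured. It called this list in 5 of the other splits, but each of those keeps part of any group difference. The block rests on 1 treated array, so a share of the slide in the size of the rise stays open. RNA of dividing red blood cell precursors could carry both lists, and would then drop together on o-anisidine 2, yet the gap of that array from the other 2 treated arrays was 0.0893 for the red blood cell list and -0.62 for the mitosis list, on a single array that decides nothing. More dividing kidney cells may also have raised these genes. The DNA replication list had a median of 0.14, which bears on dividing cells of either kind. RNA of these genes in resting cells could mask a larger rise, so both explanations stay open.

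Havcr1, Fgb and Spp1 differed more among the 3 treated animals than among the controls. The slide is an unlikely cause, since o-anisidine 1 and 2 shared a slide and a scan day and differed by a median of 3.68 over these 3 genes, against a range of at most 1.62 among the controls. The scaling of the arrays is as unlikely. The 75th percentiles of o-anisidine 1 and 2 before scaling were close, 963 and 923. After it the median absolute gap over all genes between the same 2 arrays was 0.13, which follows in part from the scaling itself. Kidney damage that differed between animals is a candidate explanation, as a hypothesis only, because no measure of injury other than RNA was analysed here.

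The fall of Cryga and Crygd concerns lens proteins and is unusual for kidney. On the slide of the controls, o-anisidine 3 lay below the control mean by log2 changes of -3.90 and -4.01, against control ranges of 0.74 and 0.75. That array thus did not lie among the controls of its own slide. The block gives the same -3.90 and -4.01, close to the -4.11 and -4.05 without it. Both genes lost the call with the block, where the SE rose from 0.22 and 0.20 to 0.31 and 0.32. The block rests on 1 treated array and 3 residual degrees of freedom in place of 4. The lost calls therefore do not speak for the slide, but 1 treated array cannot settle the question, so the slide stays open. The second kept probe of Crygd had -0.0398, so the falling probe may bind another transcript, such as a related crystallin, or the flat probe may miss the Crygd transcript, and these cannot be told apart without the probe sequences.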
